A study of Rattus norvegicus with 24 samples.

How the data were processed

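Total RNA of cultured adult rat cardiomyocytes was made into poly(A)-selected libraries with a kit for short-read sequencing, per the labels' protocols. The authors deposited 1 table of expected counts, the estimated number of reads per gene, with 1 column per library for 24 libraries. Per the submitters' processing notes, STAR 2.7.10a and RSEM 1.3.1 were used with the rat build mRatBN7.2; the annotation release, trimming and strand setting are not given in the sources used here. The deposited expected counts were neither scaled nor filtered as far as the values show, and RSEM shares a read between similar sequences in proportion to its estimates, so counts of near-identical genes are uncertain. The table held 30562 Ensembl identifiers and 3 entries for the introduced fusion sequences. The fusion entries took 0.00147 to 0.657% of the counts of a library. They were left out of library sizes and gene tests, a choice made after the table was seen. Their sum was tested in a separate fit of the same model, in which it was added to the genes and to the library sizes. The labels state that ERCC spike-in RNA was added, but the table held 0 ERCC entries, so scaling on spike-ins was not used here.

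The table does not pair identifiers with gene symbols. The reference table of rat genes used here (assembly GRCr8) carries no Ensembl identifiers, and 0 of the identifiers matched it. Each of the 21 gene lists fixed before the data were examined was therefore left untested, and the rule for named genes could not be applied as written, because it asks for a symbol. At most 2 identifiers per direction are given for a comparison, those with the largest change among genes with an adjusted p under 0.05, the same direction in all 3 preparations and a mean of at least 1 CPM. Use of identifiers in place of symbols was decided after the table was seen. Identifiers with mostly fractional counts, or with a near-identical copy, were passed over as uncertain, and the next ones in rank were used. Not every identifier that met these criteria is given.

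Groups followed the treatment labels, and the preparation followed the batch label. The design text states that 3 cardiomyocyte preparations were used, and each preparation holds all 8 groups. Deviations from group means correlated across genes at 0.380 or more between libraries of the same preparation (median 0.565). Between libraries that differed in both group and preparation the correlation was at most 0.0308. Among libraries of other groups, all 24 libraries paired best with a library of their own preparation. Subtracting the mean of 3 libraries lowers correlations between preparations when those within are positive, so part of this gap comes from the centring. Preparation was kept as a block, as fixed before the data were examined. No replicate pair agreed within sampling noise (chi-square per gene 23.7 to 59.0). Whether each preparation was 1 animal is not stated, and p-values measure the spread left between libraries once preparation differences are removed.

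Expected counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16 (glmQLFit and glmQLFTest, two-sided), on all 24 libraries in 8 groups plus preparation, with TMM factors (0.916 to 1.06) and filterByExpr. The filter kept 13640 genes with at least 99.96% of each library's counts. Benjamini-Hochberg adjustment was made over these genes within a comparison, and genes with an adjusted p under 0.05 are called. Standard errors were obtained from the fold change and its F statistic. Differences of responses were contrasts in the same fit. CPM values use TMM factors, and log2 CPM a prior count of 2. Response size was the mean signed log2 difference within each preparation, tested by exact permutation. Overlaps of called lists were set beside the value n1 × n2 / N for independent lists. Fusion totals were tested in a family of 11 comparisons.

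At about 15668000 to 27278000 counts per library the median standard error of a log2 fold change between groups was about 0.09. On simulated libraries with known changes, 38% of 1.25-fold, 62% of 1.5-fold, 84% of 2-fold and 100% of 4-fold changes were called for norepinephrine in control cells, among 13640 genes with 50 changed at each size, and 6.58% of the calls were false. For Nb80 against control in vehicle these shares were 42%, 70%, 76% and 96%, with 1.39% false calls. For the difference of responses between Nb80 and control they were 16%, 50%, 74% and 92%, with 5.69% false calls. The changed genes were drawn from those above a minimum mean count, so the shares do not cover genes with the lowest counts.

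Alternatives fixed before the data were examined were RLE factors, no filter (20538 genes), at least 1 CPM in 3 libraries (12484 genes), no preparation term, only the groups compared in the fit, DESeq2 1.42.0 with its Wald test, leaving out each library and each preparation, and, for response size, another gene choice and a prior count of 0.5. Summing near-identical copies was added after the data were seen: identifiers with equal fractional counts above 5 in at least 3 libraries formed 13 sets of 39 identifiers (igraph 2.1.4). The limit of 5 was set after a run without it had joined more identifiers through small counts. Comparisons of arms with uninfected cells other than control in vehicle, and the average over 4 arms, were also added then. All results come from 1 count table, and reads were not processed again.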

Results

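Poly(A)-selected RNA was sequenced from cultured primary cardiomyocytes, the contractile cells of the heart, isolated from adult Sprague-Dawley rats. Cells were left uninfected or were infected with an adenovirus carrying 1 of 3 fusions of the red fluorescent protein mCherry and nesprin, a protein of the nuclear envelope that holds the fusion around the nucleus. The control virus was labelled as carrying mCherry-nesprin with a myc tag, which the labels of the other two do not name. The other two carried Nb80, a nanobody that binds the active conformation of beta-adrenergic receptors, or a sequence named ICL3-9. At 2 days after infection cells received water as vehicle or 10 nmol/L norepinephrine, a catecholamine that activates adrenergic receptors, for 1 hour. The 4 arms and 2 treatments gave 8 groups of 3 libraries, and each of 3 cell preparations supplied 1 library to every group. The study asked how perinuclear Nb80 and ICL3-9 alter the transcriptional state of cardiomyocytes with and without acute adrenergic stimulation.

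The 24 libraries held about 15668000 to 27278000 counts on rat genes, with a median of about 21617000. In each library the 20 most counted genes took 23.0 to 29.8% of the counts. After the filter on low counts 13640 genes were tested, and the biological coefficient of variation left after group and preparation were fitted was 5.21%. The first principal component of log2 CPM, counts scaled to the size of the library, held 36.0% of the variance and parted preparation 1 from preparations 2 and 3. Once preparation means were subtracted, the first component held 11.1% of the variance. On it the 6 libraries of the control fusion lay between 15.4 and 22.7, while the 18 libraries of the uninfected, Nb80 and ICL3-9 arms lay between -11.4 and 0.189. The second component, with 8.09% of the variance, was above 0 in each norepinephrine library and below 0 in each vehicle library. On it the Nb80 vehicle library of preparation 3 stood apart at -24.8, against -10.1 for the next lowest. Genes are given below by Ensembl identifier, since the count table held no symbols.

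**Figure D1:**
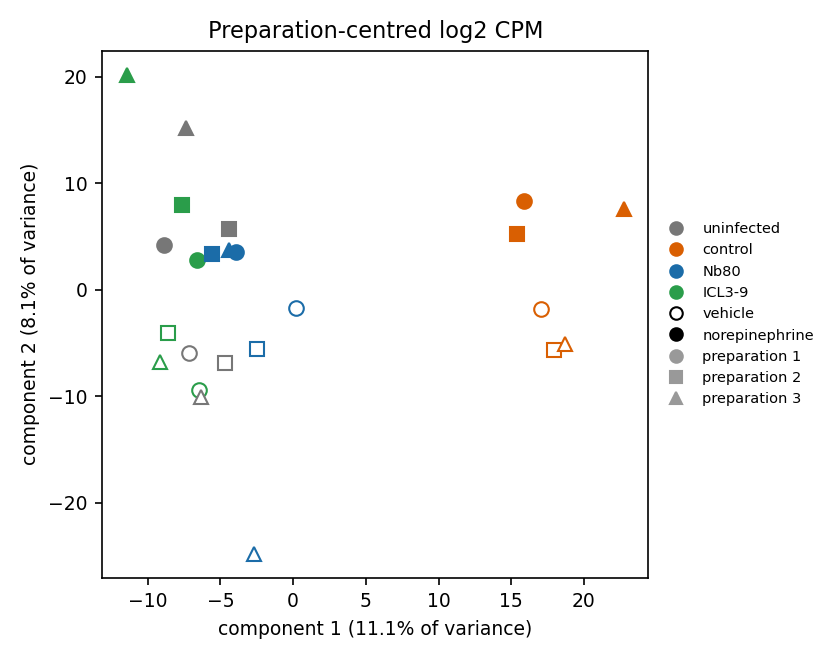
Principal components of preparation-centred log2 CPM, with component 1 (11.1% of the variance) on the horizontal and component 2 (8.09%) on the vertical axis; each point is 1 library, with colour for the arm, shape for the preparation and open or filled symbols for vehicle or norepinephrine. The 6 control fusion libraries lie above 15 on component 1, and the 18 others below 0.2.

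Transcripts of the introduced fusions were abundant in the arms that received them. In the control arm the control fusion reached 3065.5 ± 1196 CPM in vehicle and 5427 ± 2048 CPM under norepinephrine (SD, n = 3), against 10.7 ± 9.41 and 19.1 ± 7.15 CPM in uninfected cells. The Nb80 fusion reached 1262 ± 687 and 1165 ± 49.5 CPM in its own arm, and its count was at most 166 in any library of the other arms. The ICL3-9 fusion reached 1469 ± 958 and 1511 ± 499 CPM in its own arm. Reads were also assigned to the ICL3-9 fusion in each of the 6 Nb80 libraries, at 2249.5 ± 959 CPM in vehicle and 2032 ± 186 CPM under norepinephrine, with 1.80 ± 0.162 times as many as on the Nb80 fusion (SD, n = 6). Control and uninfected libraries held 49 to 308 counts there. Summed over the 3 fusions, the ICL3-9 arm carried less fusion transcript than the control arm in vehicle (log2 difference -1.12, SE 0.24, adjusted p = 0.000297 over the 11 tests of the fusion total). The difference between Nb80 and control arms in vehicle did not pass this test (log2 difference 0.18, SE 0.23, adjusted p = 0.601). Under norepinephrine both arms carried less than control cells, by -0.63 for Nb80 (SE 0.23, adjusted p = 0.0271) and -1.80 for ICL3-9 (SE 0.24, adjusted p = 8.5e-07). When placed among all genes, these 2 tests gave an adjusted p of 0.112 for Nb80 and 2.3e-05 for ICL3-9. In preparation 1, however, the Nb80 norepinephrine library held more than the control one (3455 against 3095 CPM). Preparation 3 held the highest total in the vehicle libraries of Nb80 (5457 CPM, against 2668 and 2546 CPM) and ICL3-9 (2603 CPM, against 950 and 932 CPM).

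**Figure D2:**
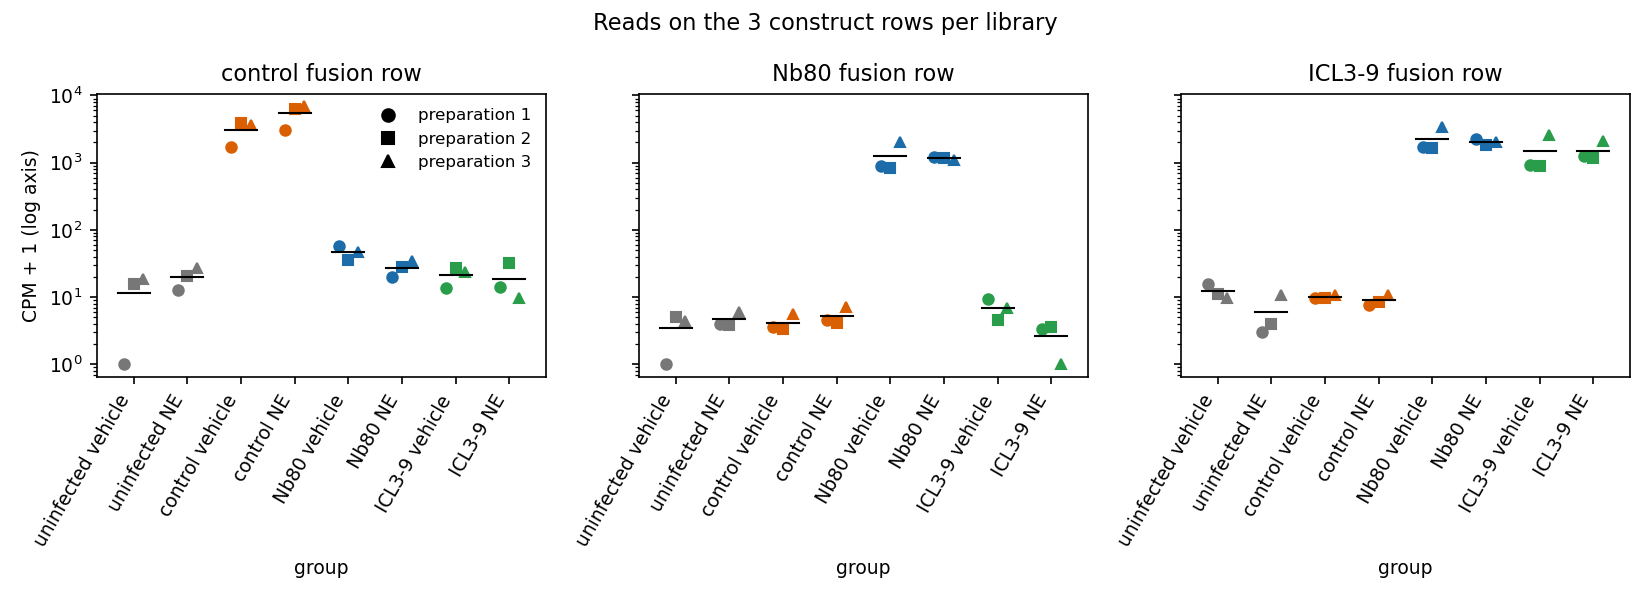
CPM + 1 on a log axis for the control, Nb80 and ICL3-9 fusions in each library (points; shape marks the preparation) of the 8 groups, with the group mean as a line. Each fusion is high in its own arm, and the ICL3-9 panel is also high in Nb80 libraries, at 2249.5 and 2032 CPM on average.

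The response to norepinephrine was measured first in uninfected cells. ENSRNOG00000001189 rose 13.1-fold, from 5.42 ± 1.58 to 71.0 ± 11.2 CPM (SD, n = 3; log2 fold change 3.72, SE 0.11, adjusted p = 1.8e-18), and ENSRNOG00000005964 rose 9.58-fold, from 2.54 ± 0.363 to 25.8 ± 10.7 CPM. ENSRNOG00000023465 fell from 42.3 ± 7.76 to 20.8 ± 4.20 CPM (log2 fold change -1.03, SE 0.14) and ENSRNOG00000004100 from 42.2 ± 14.9 to 23.8 ± 9.07 CPM (-0.85, SE 0.10). In all, 64 genes passed the test, 56 higher and 8 lower, and all 64 changed in the same direction in each of the 3 preparations. At least a 2-fold change was seen for 22 of them, 21 higher and 1 lower. Without the preparation term in the model the count was 11, and neither ENSRNOG00000023465 nor ENSRNOG00000004100 was called.

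Among identifiers with unambiguous counts and a mean of at least 1 CPM, the same pair showed the largest rises in the 3 infected arms. In control cells the call of ENSRNOG00000067271 (log2 fold change 10.17, adjusted p = 1e-08) was larger, but its counts are ambiguous, and the sum with its near-identical copies gave 0.12 (adjusted p = 0.995). ENSRNOG00000001189 rose 12.8-fold in control cells, 14.1-fold in Nb80 cells and 12.8-fold in ICL3-9 cells (log2 fold changes 3.68, SE 0.11, 3.82, SE 0.11, and 3.68, SE 0.11). ENSRNOG00000005964 rose 10.7-fold, 11.2-fold and 10.3-fold (log2 fold changes 3.42, SE 0.28, 3.48, SE 0.26, and 3.36, SE 0.26). ENSRNOG00000004100 fell by 0.83 (SE 0.10) on the log2 scale in control cells, and ENSRNOG00000069521 fell by 0.68 (SE 0.11) in Nb80 cells and by 0.71 (SE 0.11) in ICL3-9 cells, the largest fall in the latter. Both identifiers were called lower in the other arms too. For ENSRNOG00000004100 the log2 fold changes were -0.56 in Nb80 and -0.48 in ICL3-9 cells (adjusted p = 0.00135 and 0.00831). For ENSRNOG00000069521 they were -0.66 in control and -0.69 in uninfected cells (adjusted p = 0.000288 and 0.000258). ENSRNOG00000023465 fell in each of the 3 infected arms. Its falls on the log2 scale were 0.83 (SE 0.15) in control, 0.88 (SE 0.14) in Nb80 and 0.69 (SE 0.14) in ICL3-9 cells. The control call was lost without all libraries of preparation 2 (adjusted p = 0.117) or 3 (0.161), and the ICL3-9 call without those of preparation 3 (0.0758) and without 1 of 3 libraries of that arm (ICL3-9 vehicle of preparation 1, 0.201; norepinephrine of preparation 1, 0.0717; norepinephrine of preparation 3, 0.0789). The test called 72 genes in control cells (59 higher, 13 lower), 80 in Nb80 cells (63 higher, 17 lower) and 72 in ICL3-9 cells (65 higher, 7 lower). The 17 falling genes in Nb80 cells became 5 without Nb80 norepinephrine of preparation 1, 5 and 7 without Nb80 vehicle of preparations 2 and 3, 4 without Nb80 norepinephrine of preparation 3 and 6 without all libraries of preparation 3. Other settings raised the falls: Nb80 cells gave 82 higher and 66 lower with no filter, and 81 and 66 with only the groups compared. ICL3-9 cells gave 89 higher and 28 lower with no filter. The count in control cells was 67 after counts of near-identical copies were summed, and all 67 were among the 72. Of the 101 genes called in at least 1 arm, 56 were called in all 4, 51 of them higher and 5 lower throughout, and 32 were called in a single arm. The fitted direction was the same in all 4 arms for 90 of the 101 (89.1%), so a call in a single arm does not show a response of that arm alone. Control and Nb80 cells shared 54 of their 59 and 63 rising genes, where independent lists would share 0.273. Averaged over the 4 arms, a comparison added after the data were seen, norepinephrine changed 259 genes, 158 higher and 101 lower, with a median absolute change of 0.23 on the log2 scale. The balance of rises and falls was 158 to 161 without uninfected vehicle of preparation 2 and 113 to 41 without preparation 3. Without the preparation term the counts were 8 in control, 13 in Nb80, 11 in ICL3-9 and 57 for the average, and none of the falls of single identifiers given for the 3 infected arms was called.

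Whether Nb80 or ICL3-9 altered the response was tested gene by gene as a difference of responses. No gene with unambiguous counts passed the test for Nb80 against control or for ICL3-9 against control cells. The single identifier past the threshold in either test was ENSRNOG00000067271, named here after its values were seen, with adjusted p = 9.69e-05 for Nb80 minus control and 3.82e-06 for ICL3-9 minus control. It also was the single call for control minus uninfected (adjusted p = 1.24e-06). Its counts came almost wholly from preparation 2, and it is 1 of 5 identifiers that held equal fractional counts in several libraries, as near-identical copies do. The sum over the 5 was 329 to 452 in every library of preparation 2 and at most 4.15 elsewhere, and the summed counts gave log2 differences of 0.08, -0.08 and 0.10 with adjusted p of 1.00 in all 3 tests. For Nb80 minus ICL3-9 edgeR called 0 genes, with 385 at an unadjusted p under 0.05, and DESeq2 called 0 in each of the 4 tests of differing responses. At an unadjusted p under 0.05 edgeR gave 537 genes for Nb80 minus control, 504 for ICL3-9 minus control and 422 for control minus uninfected. All 4 counts lie below 5% of the 13640 genes, the share expected with no difference in any gene. Adjustment over the 259 genes of the averaged response alone, a list chosen on these libraries and so not independent evidence, left the same identifier as the single call in the 3 tests and 0 for Nb80 minus ICL3-9. The median standard error of a difference of responses was 0.13 on the log2 scale, and in simulated libraries 16% of 1.25-fold, 50% of 1.5-fold and 74% of 2-fold differences between Nb80 and control were called. The counts were 0 without control vehicle, control norepinephrine, Nb80 vehicle or Nb80 norepinephrine of preparation 2 (Nb80 minus control), and 2 without control norepinephrine of preparation 3. The ICL3-9 test gave 0 without control vehicle, control norepinephrine, ICL3-9 vehicle or ICL3-9 norepinephrine of preparation 2. Control minus uninfected gave 0 without any of its libraries of preparation 2, and 2 without uninfected vehicle of preparation 1 or control norepinephrine of preparation 3. With no filter edgeR called 7 for Nb80 minus control, 6 for ICL3-9 minus control and 2 for control minus uninfected. Without all libraries of preparation 3 these counts were 2, 6 and 2, and Nb80 minus ICL3-9 gave 1.

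The overall size of the response was compared on the 64 genes called in uninfected cells, which supply no library to these comparisons. Their mean change, signed by direction, was 1.03 ± 0.10 on the log2 scale in uninfected cells, 0.96 ± 0.09 in control cells, 1.05 ± 0.15 in Nb80 cells and 1.02 ± 0.06 in ICL3-9 cells (SD over 3 preparations). Nb80 cells responded by 0.09 more than control cells, with a 95% interval from -0.09 to 0.27 and a higher value in 3 of 3 preparations (two-sided exact permutation p = 0.4, paired exact p = 0.25). ICL3-9 cells responded by 0.06 more, with an interval from -0.18 to 0.30 and a higher value in 2 of 3 preparations (exact permutation p = 0.4, paired exact p = 0.5). With 3 values per arm these tests cannot go below 0.1, or 0.25 when paired. Over the 22 genes that changed at least 2-fold in uninfected cells, the difference for Nb80 was 0.16, with an interval from 0.05 to 0.28 (exact permutation p = 0.5, paired exact p = 0.25), and that for ICL3-9 was 0.07, with an interval from -0.40 to 0.54 (exact permutation p = 0.7, paired exact p = 0.5). The intervals rest on 3 preparation differences and assume that these are normally distributed.

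**Figure D3:**
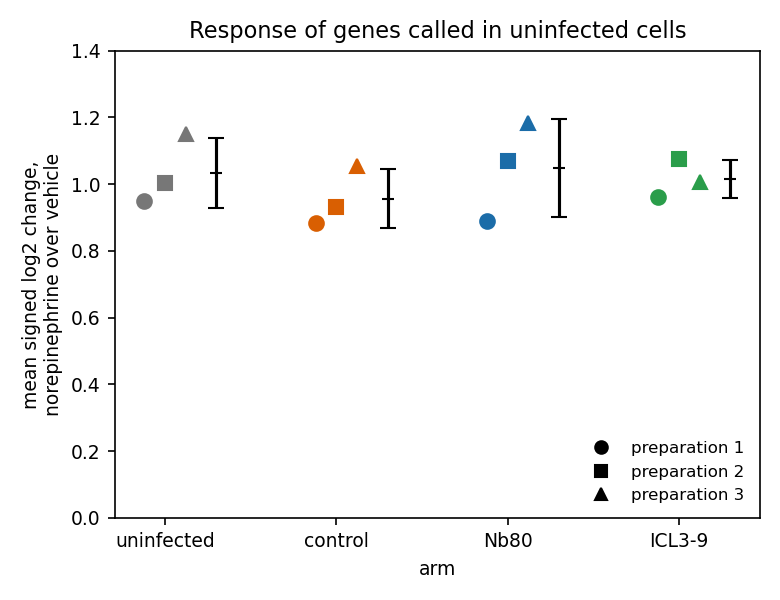
Mean signed log2 change (norepinephrine over vehicle) of the 64 genes called in uninfected cells, per arm; points are the 3 preparations, and the bar beside them is the mean and SD. All 12 values lie between 0.88 and 1.18.

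Control fusion cells were compared with uninfected cells in vehicle, to show the effect of infection together with the control protein. ENSRNOG00000036913 rose 8.45-fold, from 23.2 ± 3.41 to 195 ± 44.4 CPM (SD, n = 3; log2 fold change 3.08, SE 0.13, adjusted p = 1.59e-14), and ENSRNOG00000000579 rose 5.96-fold, from 2.37 ± 0.729 to 15.6 ± 11.1 CPM. Among identifiers with unambiguous counts, a mean of at least 1 CPM and the same direction in all 3 preparations, ENSRNOG00000017716 showed the largest fall (log2 fold change -1.41, SE 0.37, adjusted p = 0.013), a call lost without the control library of preparation 2 (adjusted p = 0.115) and without preparation 2 (0.134) or 3 (0.0733). In total 1541 genes differed, 714 higher and 827 lower in control cells, with a median absolute change of 0.24 on the log2 scale, and 49 changed at least 2-fold. Under norepinephrine, in a comparison added after the data were seen, 1444 genes differed (764 higher, 680 lower), and 422 of the rising and 417 of the falling genes were called in both conditions, where independent lists would share 40.0 and 41.2. Without preparation 3 the calls under norepinephrine were 366 higher and 503 lower. Without the preparation term the counts were 35 in vehicle and 36 under norepinephrine, and ENSRNOG00000000579 and ENSRNOG00000017716 were not called in vehicle. Leaving out single libraries gave 998, 993 and 1019 in vehicle (uninfected preparations 1, 2 and 3) and 870 and 1026 (control preparations 2 and 3), and under norepinephrine 811, 952 and 956 (uninfected preparations 1, 2 and 3) and 927 and 949 (control preparations 1 and 2).

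Nb80 cells differed from control fusion cells in vehicle by 693 genes, 364 higher and 329 lower. ENSRNOG00000012007 stood at 25.6 ± 1.72 CPM in Nb80 and 10.4 ± 0.466 CPM in control cells (SD, n = 3; log2 fold change 1.29, SE 0.09, adjusted p = 2.98e-10), beside 26.7 ± 2.51 CPM in uninfected cells. ENSRNOG00000063031 was 2.05-fold higher than in control cells. ENSRNOG00000036913 was lower, at 56.0 ± 19.6 CPM (log2 fold change -1.84, SE 0.12, adjusted p = 1.31e-10), and so was ENSRNOG00000000579, at 2.56 ± 1.76 CPM (log2 fold change -2.57, SE 0.24). Under norepinephrine 870 genes differed, 405 higher and 465 lower, among them ENSRNOG00000012007 (log2 fold change 1.34, SE 0.09), ENSRNOG00000025581 (-2.34, SE 0.30) and ENSRNOG00000000579 (-2.08, SE 0.24). The balance of higher and lower was 183 to 131 without preparation 1 and 263 to 201 without preparation 3. In both conditions 203 genes were called higher and 176 lower. Genes lower in Nb80 than in control cells under norepinephrine included 298 that were higher in control than in uninfected cells in vehicle, out of 465, and 285 of the 405 higher ones had been lower there. These lists come from separate libraries, and independent lists would share 24.3 and 24.6. Without the preparation term ENSRNOG00000000579 was called in neither condition and ENSRNOG00000025581 not under norepinephrine, the counts were 13 in vehicle and 19 under norepinephrine, and with only the groups compared in the model 324 in vehicle. Leaving out a single library gave 431, 439 and 400 in vehicle (control preparations 1, 2 and 3) and 389 (Nb80 preparation 2), and under norepinephrine 435, 496 and 555 (control preparations 1, 2 and 3) and 564, 401 and 443 (Nb80 preparations 1, 2 and 3).

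ICL3-9 cells differed from control fusion cells by 1393 genes in vehicle, 619 higher and 774 lower. ENSRNOG00000021029 rose 4.60-fold, from 7.18 ± 5.23 to 35.4 ± 32.1 CPM (SD, n = 3; log2 fold change 2.20, SE 0.29, adjusted p = 1.76e-05), and it stood at 6.98 ± 4.50 CPM in uninfected and 5.72 ± 4.29 CPM in Nb80 cells. The size of this rise varied, from 1.15 to 1.60, from 10.4 to 39.1 and from 10.0 to 65.4 CPM in preparations 1, 2 and 3, and the call was lost without the preparation term (adjusted p = 0.864). ENSRNOG00000036913 was lower than in control cells (log2 fold change -2.21, SE 0.12, adjusted p = 6.1e-12), and ENSRNOG00000000579 also was (-2.14, SE 0.23). Without preparation 3 the vehicle calls were 336 higher and 273 lower. Under norepinephrine 1566 genes differed, 718 higher and 848 lower, and 341 higher and 469 lower genes were called in both conditions. Of the 848 lower genes 417 were higher in control than in uninfected cells in vehicle, and of the 718 higher genes 347 were lower there, where independent lists would share 44.4 and 43.5. Without the preparation term ENSRNOG00000000579 was not called in vehicle, the counts were 24 in vehicle and 33 under norepinephrine, and with only the groups compared in the model 516 and 1012. Leaving out single libraries gave 893 and 805 in vehicle (control preparations 2 and 3) and 855 and 772 (ICL3-9 preparations 2 and 3), and under norepinephrine 979 and 1002 (control preparations 2 and 3) and 926 and 934 (ICL3-9 preparations 2 and 3).

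Differences of the Nb80 and ICL3-9 arms from control cells overlapped widely. Nb80 libraries also held reads on the ICL3-9 fusion, so it stays open whether Nb80 cells carried that fusion too, which would bear on the overlap. Control cells themselves differed from uninfected cells by 1541 genes in vehicle and 1444 under norepinephrine. Nb80 cells differed from uninfected cells by 2 and 1 genes, and ICL3-9 cells by 126 and 3. Much of the overlap may thus reflect the departure of control cells, and it does not by itself show an effect common to Nb80 and ICL3-9. In vehicle 248 genes were higher in both and 268 lower in both, where independent lists would share 16.5 and 18.7. Under norepinephrine 286 were higher and 366 lower in both, against 21.3 and 28.9 for independent lists. Both comparisons used the same control libraries. The covariance of their log2 fold changes across genes was 0.05 in vehicle and 0.05 under norepinephrine. Simulated libraries, with both arms unchanged from a simulated control group, gave 0.02 and 0.02. The control libraries themselves did not enter, so the simulations show what a shared group gives under the noise of the fit. The correlation across genes, which are not independent replicates, was 0.611 and 0.656, against 0.507 and 0.501 as the mean of 20 simulations. Calls were fitted in 5 of these per condition and gave 0 shared genes. With no gene changed in either arm, few or no calls arise in either list, so this outcome was set by the simulation. It does not show how far shared controls raise the overlap of the real lists. With 3 control libraries no split leaves 2 in each part. Nb80 against control in vehicle was not set against ICL3-9 against control under norepinephrine, a pair that shares no library. Part of the excess may therefore come from the shared controls.

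Nb80 and ICL3-9 cells were closer to each other in vehicle, the condition in which this comparison was run. The caveat on reads of the ICL3-9 fusion in Nb80 libraries applies here too. In vehicle 16 genes differed, 6 higher and 10 lower in Nb80 cells. The largest difference was that of ENSRNOG00000021029 (log2 fold change -2.49, SE 0.30, adjusted p = 0.000136), which lost its call without preparation 2 (adjusted p = 0.167). ENSRNOG00000053272 was 1.54-fold higher in Nb80 cells (log2 fold change 0.62, SE 0.12, adjusted p = 0.0253). That call was lost without Nb80 of preparation 1 (adjusted p = 0.0602) or 2 (0.241), without ICL3-9 of preparation 2 (0.140) or 3 (0.483), and without all libraries of preparation 2 (0.697) or 3 (0.161). The count rested on single libraries: it was 121 without ICL3-9 of preparation 1, 3 without Nb80 of preparation 1, 3 without Nb80 or ICL3-9 of preparation 2, 6 without Nb80 of preparation 3 and 2 without ICL3-9 of preparation 3. Without the preparation term it was 0, with no filter 130, with only the groups compared 56, and with DESeq2 49.

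The Nb80 and ICL3-9 arms were also compared with uninfected cells, after the data were seen. ENSRNOG00000036913 was higher in Nb80 cells in both conditions, 2.36-fold in vehicle (log2 fold change 1.24, SE 0.14, adjusted p = 2.67e-05) and 1.96-fold under norepinephrine (0.97, SE 0.14, adjusted p = 0.00272), the latter call being lost without Nb80 of preparation 1 (adjusted p = 0.0847) or uninfected cells of preparation 3 (0.0815) and without all libraries of preparation 1 (0.198). The test called 2 genes in vehicle and 1 under norepinephrine in Nb80 cells, and 126 (47 higher, 79 lower) and 3 in ICL3-9 cells. The other call in Nb80 cells in vehicle and 1 of the 3 in ICL3-9 cells was ENSRNOG00000067271, whose counts are ambiguous, and another of the 3 was ENSRNOG00000013589 (log2 fold change 0.86, SE 0.15, adjusted p = 0.0359). The latter was lost without uninfected cells of preparation 1 (0.0559), 2 (0.332) or 3 (0.114), without ICL3-9 of preparation 2 (0.410) or 3 (0.0735), and without all libraries of preparation 2 (0.858) or 3 (0.170). ENSRNOG00000021029 was higher in ICL3-9 cells under norepinephrine (1.90, SE 0.29, adjusted p = 0.0045), a call lost with DESeq2 (adjusted p = 0.0821) and without uninfected cells of preparation 2 (0.192) or 3 (0.114) or ICL3-9 of preparation 3 (0.0735), and without all libraries of preparation 2 (0.721) or 3 (0.122). The balance of higher and lower genes among the 126 moved with the filter and the libraries used: 160 to 136 with no filter, 99 to 85 without preparation 1, 6 to 4 without preparation 3, 57 to 59, 6 to 31 and 12 to 10 without uninfected vehicle of preparations 1, 2 and 3, and 12 to 38 without ICL3-9 vehicle of preparation 2. The 126 became 262 without ICL3-9 of preparation 1, 50 and 8 without ICL3-9 of preparations 2 and 3, 37 and 22 without uninfected cells of preparations 2 and 3, and 0 without the preparation term, as did the 3 other counts of these arms. The 3 became 33 without ICL3-9 of preparation 1 and 0 without uninfected cells of preparation 2. They became 1 without ICL3-9 of preparations 2 or 3 or uninfected cells of preparation 3. The Nb80 count in vehicle was 1 without Nb80 or uninfected cells of preparation 2. That under norepinephrine was 0 without Nb80 of preparation 1 or uninfected cells of preparation 3. Without all libraries of preparation 2 the 126 became 3. With only the groups compared the 126 became 7, the 3 became 20, and the Nb80 count under norepinephrine became 13. The 126 and the 3 became 296 and 50 with no filter, and 177 and 16 with DESeq2.

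**Figure D4:**
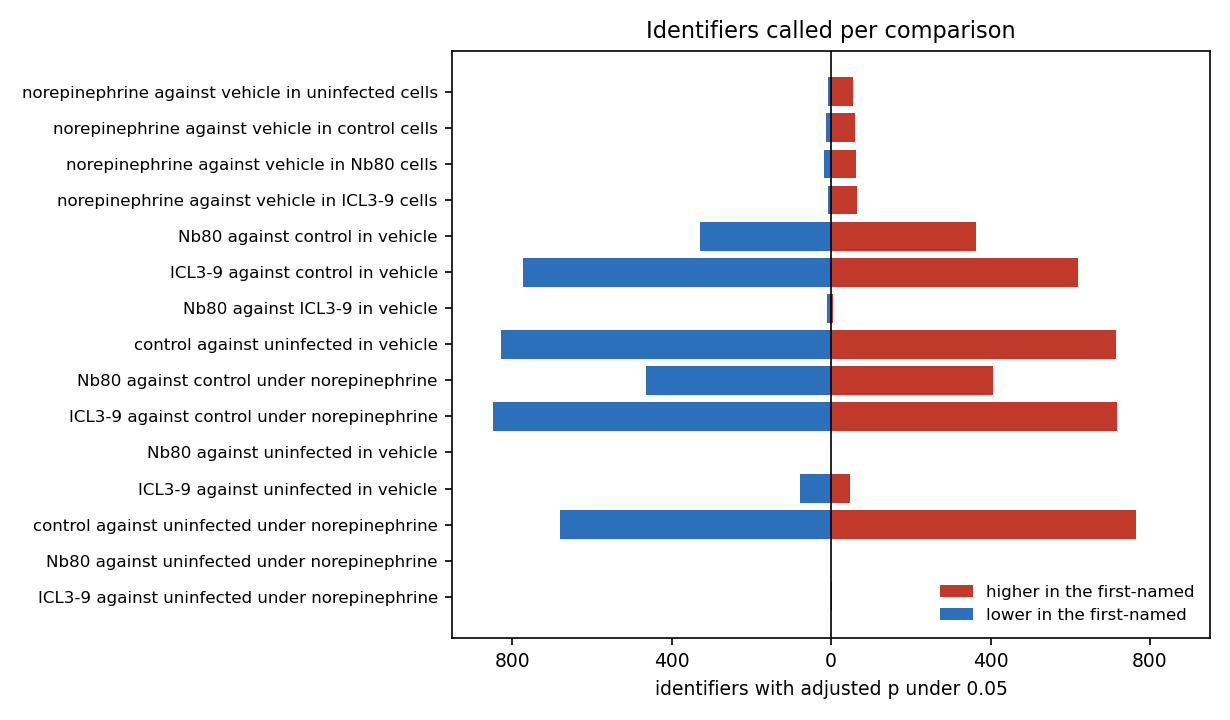
Genes with adjusted p under 0.05 in each pairwise comparison, drawn to the right when higher and to the left when lower in the group named first. The 6 longest bars on either side belong to comparisons with control fusion cells, from 693 genes for Nb80 against control in vehicle to 1566 for ICL3-9 against control under norepinephrine.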

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

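The tests in this part of the fusion total, of the summed copies and of the ratio between fusions were chosen after the results had been seen. No group held more than 3 libraries, so no library was tested for standing apart from its group.

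ENSRNOG00000067271 responded differently to norepinephrine between arms by the test of the difference itself, with adjusted p = 9.69e-05 for Nb80 minus control, 3.82e-06 for ICL3-9 minus control and 1.24e-06 for control minus uninfected. In control vehicle cells of preparation 2 it held 0 counts while the sum with its 4 near-identical copies was 397, and in control norepinephrine cells of that preparation it held 451 counts of a sum of 451. Reads split between copies in an arbitrary way may account for the calls: after summing, the largest of the 3 log2 differences was 0.10 in size. The summed set had counts in preparation 2 almost alone. A difference in genotype between preparations, since libraries of the others held at most 4.15 counts over all copies, was not tested and stays open as the reason that the set was read in preparation 2.

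Reads on the ICL3-9 fusion appeared in Nb80 libraries at a mean of 2249.5 CPM in vehicle and 2032 CPM under norepinephrine, against at most 14.4 CPM in an uninfected library. Reads shared between the sequences of the fusions by the counting, and a virus stock that holds both, are candidate explanations, and they cannot be told apart here, because both give a steady ratio to the Nb80 fusion. That ratio varied by 9.01% (CV) over the 6 Nb80 libraries. The reverse was not seen, since the Nb80 fusion held at most 8.30 CPM in an ICL3-9 library. The fusion sequences themselves were not used here.

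The total of fusion reads rose under norepinephrine in control cells (log2 fold change 0.81, SE 0.23, adjusted p = 0.00526 over the family of 11 tests and 0.251 when placed among all genes) by 1.82-fold, 1.64-fold and 1.88-fold in preparations 1, 2 and 3. The response of this total differed between Nb80 and control cells by -0.82 on the log2 scale (SE 0.33). The adjusted p was 0.0373 over the family and 0.9998 when placed among all genes. The ratios in Nb80 cells were 1.295, 1.20 and 0.578 in preparations 1, 2 and 3. For ICL3-9 minus control the difference was -0.68 (SE 0.33, adjusted p = 0.0767 over the family and 0.9999 among all genes). Much of the Nb80 difference came from preparation 3, where the Nb80 vehicle library held the highest vehicle total (5457 CPM), and the test was not repeated without that library.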

How the results depend on the processing

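The alternatives were planned, except the summing of near-identical copies and every run of the comparisons added later, which were chosen after seeing the data. RLE factors kept all counts within 1.5 times. Of 145 values of counts and response sizes under settings other than leaving out libraries, 95 stayed within bounds and 50 moved. The bound was 1.5 times for counts, while a response size stayed within bounds when it kept its sign. Of 957 values of the printed or ranked identifiers, 812 kept their call, 145 lost it and 0 changed sign.

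Without the replicate block, leaving preparation differences in the error, norepinephrine called 11 genes in uninfected, 8 in control, 13 in Nb80 and 11 in ICL3-9 cells (all higher), and 57 averaged over arms (51 higher, 6 lower); all of these were also called with the block. The counts were 13 and 19 for Nb80 against control (vehicle, norepinephrine), 24 and 33 for ICL3-9 against control, 35 and 36 for control against uninfected, and 0 for Nb80 against ICL3-9, for Nb80 or ICL3-9 against uninfected in both conditions and for the differences of responses.

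With only the groups compared, counts were 147 for norepinephrine in Nb80 cells (81 higher, 66 lower), 2 for the difference of responses between Nb80 and control, 324 for Nb80 and 516 for ICL3-9 against control in vehicle, 1012 for ICL3-9 against control under norepinephrine, 56 for Nb80 against ICL3-9, 1 and 13 for Nb80 against uninfected (vehicle, norepinephrine), and 7 and 20 for ICL3-9 against uninfected. The cause was not tested. With no filter they were 148 for norepinephrine in Nb80 (82 higher, 66 lower), 117 in ICL3-9 cells (89 higher, 28 lower) and 390 averaged, 7, 6 and 2 for the differences of responses (Nb80 and ICL3-9 minus control, control minus uninfected), 130 for Nb80 against ICL3-9, 8 and 7 for Nb80 against uninfected, and 296 and 50 for ICL3-9 against uninfected; the cause was not tested. At least 1 CPM in 3 libraries gave 7 for ICL3-9 against uninfected under norepinephrine. DESeq2 gave 49 for Nb80 against ICL3-9, including all 16, 16 for ICL3-9 against uninfected under norepinephrine, and 0 for the 3 differences of responses with 1 call. Summing copies gave 0 for these 3 and 1 for Nb80 against uninfected in vehicle.

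Leaving out 1 library or 1 preparation, counts ranged from 48 to 64, 40 to 69, 50 to 90 and 46 to 78 for norepinephrine in uninfected, control, Nb80 and ICL3-9 cells, and from 154 to 329 averaged. They ranged from 0 to 2, 0 to 6, 0 to 1 and 0 to 2 for the differences of responses (Nb80 minus control, ICL3-9 minus control, Nb80 minus ICL3-9, control minus uninfected). Ranges were 121 to 474 and 166 to 564 for Nb80 against control (vehicle, norepinephrine), 369 to 1293 and 411 to 1253 for ICL3-9 against control, 0 to 121 for Nb80 against ICL3-9, and 330 to 1285 and 432 to 994 for control against uninfected. They were 1 to 8 and 0 to 1 for Nb80, and 3 to 262 and 0 to 33 for ICL3-9 against uninfected. Without preparation 2 the norepinephrine counts were 40 in control, 50 in Nb80 and 46 in ICL3-9 cells. Fewer libraries entered these fits, and with 1 preparation out each group holds 2. Response size ranged from 0.07 to 0.13 for Nb80 minus control and from 0.02 to 0.11 for ICL3-9 minus control.

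Not run were scaling on spike-ins, the gene lists with either correlation and response size over fixed lists, for want of entries or symbols. The average over arms uses all groups, so no fit of only the groups compared was made. At this depth and with 3 preparations a 1.25-fold difference of responses was called for 16% of simulated genes; whether depth or the spread between libraries sets this was not tested.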

Other observations

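The tests of the vehicle level of norepinephrine-responsive genes were set before their values were seen. Those of the control fusion arm and of other splits of the libraries were chosen after the results had been seen.

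Genes that respond to norepinephrine were compared between arms in vehicle, each time with genes called in an arm that supplies no library to the difference. Over 72 genes called in ICL3-9 cells, the level in Nb80 cells differed from control cells by 0.048 ± 0.034 on the log2 scale (SD, n = 3), positive meaning towards the norepinephrine-treated state. Over 80 genes called in Nb80 cells, ICL3-9 differed from control cells by 0.048 ± 0.081, and control from uninfected cells by -0.10 ± 0.08, with -0.03, -0.19 and -0.09 in preparations 1, 2 and 3. The hypotheses were that Nb80 or ICL3-9 lowers the vehicle level of these genes by 0.05 or more, or that the control fusion raises it by as much. None was borne out, as each mean lay off its bound by more than the SD over preparations. With 3 preparations a margin of 1 SD does not exclude such changes. For ICL3-9 minus control the values were -0.045, 0.106 and 0.083 in preparations 1, 2 and 3.

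Control fusion libraries stood apart: over the 1541 genes that differed between control and uninfected cells in vehicle, the mean signed difference from uninfected cells under norepinephrine, in separate libraries, was 0.24 ± 0.02 for control, 0.04 ± 0.02 for Nb80 and 0.03 ± 0.02 for ICL3-9 cells (log2, SD, n = 3). Over the 1444 genes that differed under norepinephrine, measured in vehicle, it was 0.25 ± 0.02, 0.05 ± 0.01 and 0.03 ± 0.01. A response to adenoviral infection as such would move all infected arms. Nb80 and ICL3-9 cells showed 15.6 and 12.3% of the control change in the first measure and 22.0 and 13.9% in the second. This argues against infection as the main cause only if the arms were infected to a similar degree. That was not measured apart from the fusion reads, of which ICL3-9 cells carried fewer. A larger amount of fusion transcript in control cells is argued against by the 3 preparation-matched pairs (preparations 1 and 3 in vehicle, 1 under norepinephrine) in which the control library carried fewer fusion reads than the Nb80 library, where the control value was still higher by 0.16 to 0.20, beyond the largest SD within a group of 0.02. This holds for the total, in which reads on the ICL3-9 fusion in Nb80 libraries count as fusion transcript; on the fusion of each arm alone control cells held more in all 3 pairs (1689 against 890, 3658 against 2055 and 3085 against 1208 CPM), so that measure gives no such pair. Across preparations, Nb80 and ICL3-9 vehicle libraries of preparation 3 held more of their own fusion (2055 and 2575 CPM) than the control vehicle library of preparation 1 (1689 CPM) and scored 0.05 and 0.04 against 0.23, which goes against the amount by that measure too but rests on 1 control library, so it stays open there. Each arm received its own virus, so an effect of the virus stock or vector, of the control protein itself or the myc tag that its label names, or of Nb80 and ICL3-9 countering an effect of the shared fusion may each be involved, and these stay open as untested hypotheses.

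Each comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05. The real split gave the highest count, 1 of 10, in 9 comparisons. Real and next highest counts were 64 and 1 for norepinephrine in uninfected, 72 and 5 in control, 80 and 0 in Nb80 and 72 and 4 in ICL3-9 cells. They were 693 and 2 for Nb80 and 1393 and 3 for ICL3-9 against control in vehicle, 870 and 0 and 1566 and 2 under norepinephrine, and 1541 and 6 for control against uninfected. Among the 3 other splits that, like the real one, part all 3 preparation pairs, the highest counts were 0, 1, 0 and 0 for norepinephrine in the same order, 2 and 2 in vehicle, 0 and 1 under norepinephrine, and 6. For Nb80 against ICL3-9 in vehicle 2 of 10 splits gave at least the real 16, and the other, with Nb80 of preparations 1 and 2 and ICL3-9 of preparation 1 against the rest, gave 77. That split keeps preparations 1 and 3 whole on opposite sides and points to a structure of these 6 libraries beyond the arm, whose cause was not tested; the splits that part all 3 pairs gave at most 1. For differences of responses, 6 of 10 splits gave at least the real count of 1 for Nb80 minus control (highest other 1), ICL3-9 minus control (1) and control minus uninfected (2). In all 3 tests these were the splits that put the arms of preparation 2 on opposite sides, and the remaining splits gave 0. The single real call, ENSRNOG00000067271, was read almost only in preparation 2, so these splits cannot decide on the grouping by arm. For Nb80 minus ICL3-9 the real count was 0, which any split reaches (highest other 1).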
